A study of Mus musculus with 36 samples.

How the data were processed

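RNA sequencing was done by the authors on 36 mouse heart libraries from total RNA extracted with Trizol, run on an Illumina GA-2 or Hi-Seq per the labels. The deposited values are FPKM, levels scaled to transcript length and library size, in a table made by the authors with 1 column per library and 36128 gene models under 32750 symbols. Per the submitters' processing notes the tools were Bowtie 0.12.7, TopHat 1.3.2, Cufflinks 1.2.1 and Cuffdiff, whose version is not stated, on mouse genome build mm9; the annotation is not stated. Depth per library is unknown, and no count-based model was used. All 36 columns were used.

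Values were taken as log2(FPKM + 1). For each preparation (12 isolated, 16 ventricle and 8 explant libraries) a model of group means was fitted with limma 3.58.1 under R 4.3.3, with the variance prior following mean expression. Genes with an FPKM of at least 1 in at least 2 libraries of the fit were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold, and all tests were two-sided. The comparisons were isolated P4 against P0, isolated resection against sham at day 7, ventricle P7 and adult against P0, ventricle resection against sham at day 1 and day 7, explant 24 h and 72 h against 0 h, the difference between the ventricle resection effects at day 7 and day 1, and the difference between the isolated and ventricle effects at day 7, the last from a fit over all 36 libraries. Explants at 48 h and ventricle at P4 entered the fits but no comparison. Figures were drawn with Matplotlib 3.10.9 and NumPy 2.4.6 under Python 3.11.15.

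The named genes were chosen by a rule. In each comparison these were the 8 called genes with the largest increase and the 8 with the largest decrease that had a group mean of at least 5 FPKM and replicates that did not overlap between the groups, leaving out unnamed gene models. From each list the 2 called members with the largest change were added, or, where none was called, at most 2 with the smallest p. Always named were Myh6, Myh7, Tnni1, Tnni3, Nppa, Nppb, Il13, Il4ra, Il13ra1, Ccnb1 and Mki67. The text gives a selection of these. Mapt and Myl7 in isolated cells at P4, Ankrd1 in isolated cells at day 7, Sftpc in ventricle at day 7 and the genes called in both preparations were named after their values were seen.

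The 25 gene lists, 13 of pathways and 12 of cell types, hold 433 members, of which 404 were found in the table and the others were not analysed here. Lists were tested against other genes with camera in limma at a preset correlation of 0.01 and with an estimated correlation, with the rotation test fry beside it, and members were also adjusted over the list alone. Skeletal muscle and adipocyte lists had too few tested genes for a set test in some comparisons; the adipocyte gene Car3 was called in adult ventricle alone, at 0.93. Mean marker levels per library were compared between resection and sham, and between P4 and P0 in isolated cells, with exact permutation tests, whose smallest p is 0.1 for 3 against 3 and 0.333 for 2 against 2. A list of 27 lung genes and a list of 6 further atrial genes were written after the largest changes were seen; 9 of the lung genes and the 6 atrial genes had not been looked at when they were listed. They were compared with random lists matched on mean expression, the 9 lung genes without the expression filter, since that filter kept 4 of them.

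Genes that rose or fell from P0 to the adult ventricle formed the maturation sets. Replicate numbers were checked for pairing by correlating the deviations from group means across groups: they correlated in explants, and not throughout in isolated cells or ventricle. Recovery was simulated with 67, 67 and 66 genes changed 1.5, 2 and 4-fold, and may differ where more change. In isolated cells 10.4%, 59.7% and 95.5% were recovered for P4 against P0 (12693 genes tested) and 1.49%, 53.7% and 97.0% for resection against sham (12691 genes). In ventricle the shares were 31.3%, 89.6% and 100% for P7 (13434 genes), 23.9%, 83.6% and 100% for adult (13403 genes), 32.8%, 88.1% and 100% for day 1 (13403 genes) and 31.3%, 89.6% and 100% for day 7 (13421 genes). In explants they were 0%, 1.49% and 78.8% at 24 h (11799 genes) and 0%, 4.48% and 78.8% at 72 h (11793 genes). For the difference between day 7 and day 1 they were 4.48%, 61.2% and 100% (13416 genes), and for that between preparations 0%, 14.9% and 93.9% (13636 genes).

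Alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, the replicate number as a block, a single fit over all libraries, fits on the compared groups alone, no variance trend, a 2-fold minimum, an estimated correlation, maturation sets from isolated P4 or ventricle P7 against P0, maturation sets without the cell-cycle lists, and leaving out each replicate in turn. Added after the data were seen were single values of 0 in genes with at least 20 FPKM in every other library treated as missing, fits on the ventricle age or surgery libraries alone, the endothelial marker level as a covariate in isolated cells, and the removal of lung and atrial genes.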

Results

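Gene expression was measured by RNA sequencing in 36 libraries of mouse heart that fall into 16 groups. Isolated cardiomyocytes, purified on Miltenyi columns, were sampled at postnatal day 0 (P0), at P4, and 7 days after resection of heart tissue or a sham operation, with n = 3 in each group. Dissociated adult cardiomyocytes kept in culture (explants) were sampled at 0, 24, 48 and 72 h, with n = 2. Whole ventricle was sampled at P0, P4, P7 and in adults, and 1 and 7 days after resection or sham, with n = 2 in each of these 8 groups. The mice were of the CD-1 background. The values are FPKM, which do not form whole multiples of a count, so the depth of each library is unknown and no counting interval is given. Between 10454 and 13134 gene models per library had an FPKM of at least 1. The labels do not state that replicates came from separate animals, so the p-values measure the spread between samples only. The 25 lists of genes, the comparisons and the rule for naming genes were written before the data were examined; a list of 27 lung genes and a list of 6 further atrial genes were added afterwards.

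**Figure D1:**
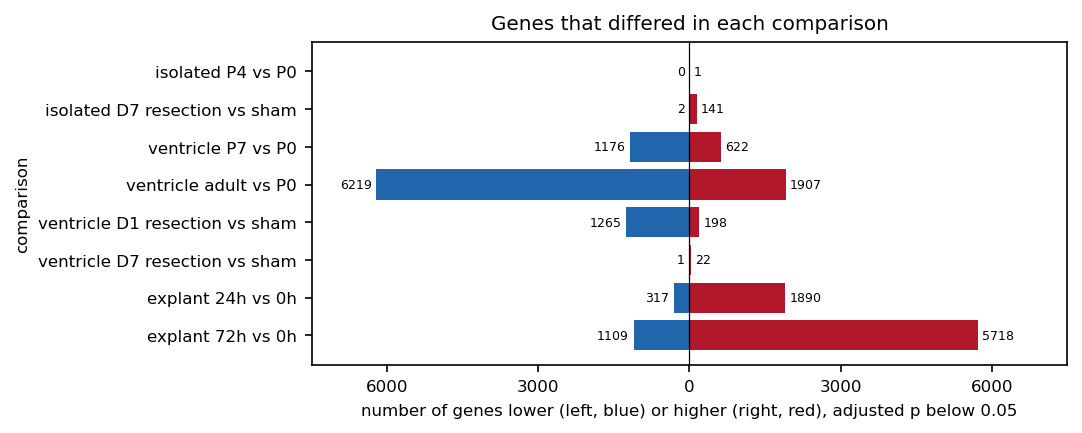
Number of genes that differed in each comparison (adjusted p under 0.05, limma), with lower genes to the left and higher genes to the right of 0. The bars range from 1 gene in isolated cells at P4 against P0 to 6219 lower genes in adult ventricle against P0; the numbers beside the bars are the counts.

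The postnatal comparisons of whole ventricle asked which genes change as the heart loses its neonatal state. From P0 to P7 part of the cell-cycle, fetal and atrial genes fell. Some genes of the sarcomere rose, a balance that the scaling decided for the contractile list. From P0 to the adult all tested genes of the cell-cycle lists fell, as did 21 of 23 extracellular matrix genes. Of fatty acid oxidation genes 16 of 27 rose and 2 fell, and of respiratory genes 19 of 36 rose and 1 fell. As sets none of these lists held with an estimated correlation (adjusted p of 0.334 for fatty acid oxidation and 0.274 for the others). The median of all genes was itself shifted, by -0.14 at P7 and by -0.36 in the adult on the log2 scale, and list medians are to be read against it.

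At P7, 622 genes were higher and 1176 lower than at P0 among 14201 tested. The share of higher genes was 34.6%, and it was 57.4% after median-of-ratios scaling and 54.9% after quantile normalization. Trim72 (tripartite motif 72) rose by 3.27 and Rpl3l by 3.12 on the log2 scale, the latter from 4.42 ± 0.303 to 46.6 ± 8.07 FPKM (SD, n = 2). Xirp2 rose by 3.59, Tuba8 by 3.64 and Ckmt2 by 2.67. The slow skeletal troponin I gene Tnni1 fell by 2.75, from 1199 ± 117 to 182 ± 61.8 FPKM (SD, n = 2, adjusted p = 5.1e-05), and the beta-myosin gene Myh7 fell by 1.58. Myh6 changed by 0.13 (adjusted p = 0.77). Dlk1, Hif3a and Hey2 fell by 3.90, 3.07 and 2.99. Of 28 tested genes of DNA replication 9 fell and none rose, or 14 adjusted over the list alone, with Uhrf1 (-0.90) and Mcm6 (-0.84) among them. Of 29 mitosis genes 7 fell, or 18 adjusted over the list alone and 4 after median-of-ratios scaling, while Mki67 differed by 0.02 (adjusted p = 0.98). Both lists were lower as sets (adjusted p = 1.1e-04 and 7.8e-05), though not with an estimated correlation (adjusted p = 0.46 and 0.466) or with the limma rotation test fry (adjusted p = 0.0596 and 0.0685).

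Of 14 fetal cardiac genes 8 fell at P7 and none rose, or 9 adjusted over the list alone, with Myl7 at -5.02 and Myl4 at -4.56. These are atrial genes too: 5 of 8 atrial genes fell, or 7 adjusted over the list alone, and the P0 ventricle libraries themselves differed in Myl7 (459 and 70.6 FPKM). Contractile genes rose in 5 of 19 cases (6 adjusted over the list alone), among them Trim54 (1.68) and Lmod2 (0.98), with a median of 0.18 (adjusted p = 1.7e-04 as a set; adjusted p = 0.439 with an estimated correlation). Under quantile normalization 5 contractile genes rose and 3 fell, the median was 0.02 and the set no longer passed (adjusted p = 0.175). Immediate early genes rose in 9 and fell in 3 of 21 cases (10 and 3 adjusted over the list alone), with Egr1 at 1.51 and Gadd45b at -1.42. Glycolysis genes fell in 4 cases and rose in 1 of 16 (4 and 1 adjusted over the list alone), with Slc16a3 at -1.87. Fatty acid oxidation was mixed, with 1 gene higher and Acot2 (-1.01) and Cpt1a (-0.87) lower, and with 4 higher and 2 lower under either other scaling. Calcium handling genes rose in 4 cases and fell in 1, led by Trdn (1.19), and 2 respiratory genes rose, Cox8b (1.02) and Ogdh (0.81), against 5 after median-of-ratios scaling and 3 after quantile normalization.

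Among cell-type markers at P7, 6 of 9 fibroblast genes rose (6 adjusted over the list alone), with Mfap5 at 1.52, and 4 of 7 erythroid genes rose (6 adjusted over the list alone). Of 9 smooth muscle and pericyte genes 3 rose and 2 fell (6 and 2 adjusted over the list alone), with Rgs5 at 1.76. Of 8 epicardial genes 4 fell (6 adjusted over the list alone; 1 after median-of-ratios scaling) and of 6 neutrophil genes 2 fell (3 adjusted over the list alone). Macrophage, endothelial and inflammatory lists had 1 gene higher each (3, 4 and 1 after quantile normalization), and 2 skeletal muscle genes were lower adjusted over the list alone. Cardiomyocyte markers had 0 of 7 passing, with a median of 0.13 that turned to -0.32 under quantile normalization, and the Schwann list had 0 as well. Extracellular matrix genes rose in 2 cases, Col3a1 and Fbn1, and in 0 adjusted over the list alone, against 5 and 4 under the other scalings. Cytoskeleton genes fell in 3 of 20 cases. In the IL-4/IL-13 list 1 gene rose over all genes (4 after quantile normalization), and 2 rose and 1 fell adjusted over the list alone. Il13ra1 rose by 0.54 (adjusted p = 0.042), and Il4ra by 0.58 without passing the threshold (adjusted p = 0.14); Il13 was below the expression filter. The fetal list as a set was lower than other genes (adjusted p = 8.8e-06), and adjusted p = 0.228 with an estimated correlation. At the preset correlation the glycolysis, neutrophil, epicardial and atrial lists were lower as well, and the calcium, fatty acid, respiratory, matrix, IL-4/IL-13, immediate early, endothelial, fibroblast, smooth muscle, macrophage and erythroid lists higher (adjusted p from 7.2e-06 to 0.042). None of them held with an estimated correlation (adjusted p from 0.228 to 0.564), and the calcium and fatty acid lists did not pass after quantile normalization nor the IL-4/IL-13 list after median-of-ratios scaling. The count of 1798 was 482 in a single fit of all 36 libraries. It fell to 771 without P0 replicate 1, 581 without P7 replicate 1 and 788 without P7 replicate 2.

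In adult ventricle 1907 genes were higher and 6219 lower than at P0. The share of higher genes was 23.5%, against 48.4% after median-of-ratios scaling and 48.3% after quantile normalization. Tnni1 (ENSMUSG00000026418, chromosome 1, 137679641 to 137707566, mm9) fell by 9.14, to 1.12 ± 0.113 FPKM (SD, n = 2). The growth genes Igf2, Plagl1 and Dlk1 fell by 5.14, 5.15 and 5.88, and Cited1 by 5.48. Rpl3l (ENSMUSG00000002500, chromosome 17, 24864773 to 24873094) rose by 5.30 to 213 ± 20.2 FPKM (SD, n = 2), Bdh1 by 4.82, Trim72 by 4.75 and Ces1d by 4.37. The cardiac troponin I gene Tnni3 rose by 0.98 (adjusted p = 0.001) and Myh7 fell by 1.51, while Myh6 rose by 0.46 without passing the threshold (adjusted p = 0.12). The mitochondrial gene mt-Co1 was listed at 0 in both adult libraries and at 14155 ± 1578 FPKM (SD, n = 2) at P0, and no fold is given for it.

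All 28 tested replication genes and all 29 mitosis genes were lower in the adult, with the same counts adjusted over the list alone and under both other scalings. Ccna2 fell by 4.59, Top2a by 4.48, Rrm2 by 3.83, Mki67 by 3.21 and Ccnb1 by 2.79. Extracellular matrix genes fell in 21 of 23 cases (21 adjusted over the list alone), with Postn at -4.23 and Fn1 at -3.44, and cytoskeleton genes in 17 of 20, with Tubb5 at -2.48, or in 10 after median-of-ratios scaling. Fetal genes fell in 8 of 14 cases and atrial genes in 6 of 8. Respiratory genes rose in 19 and fell in 1 of 36 cases, with Cox7a1 at 2.37; 33 rose and 0 fell after median-of-ratios scaling, and 16 rose and 2 fell after quantile normalization. Fatty acid oxidation genes rose in 16 and fell in 2 of 27, with Ech1 at 1.67 and Cpt1a at -1.81, against 22 and 2 after median-of-ratios scaling and 16 and 4 after quantile normalization. Contractile genes rose in 9 of 19 cases, with Trim54 at 4.21 and Tcap at 2.93 (median 0.51, adjusted p = 2.0e-06 as a set; adjusted p = 0.274 with an estimated correlation). After median-of-ratios scaling 14 contractile genes rose and 0 fell. Under quantile normalization 6 rose and 3 fell, the median was 0.13 and the set no longer passed (adjusted p = 0.119). Calcium handling genes rose in 11 and fell in 4 of 22, with Hrc at 2.49, against 14 and 1 after median-of-ratios scaling and 11 and 6 after quantile normalization. Adjusted over the list alone the main counts were the same. None of these lists passed as a set with an estimated correlation (adjusted p from 0.274 to 0.4375).

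Of 12 macrophage and leukocyte genes 12 were higher in the adult, with Lyz2 at 3.01 and C1qa at 2.13, and 8 of 16 inflammatory genes rose, with Csf1 at 1.71. Cardiomyocyte markers rose in 3 of 7 cases (2 adjusted over the list alone), and their median of 0.46 turned to -0.08 under quantile normalization, with 1 higher and 2 lower; after median-of-ratios scaling 6 were higher. Glycolysis genes were split (2 higher and 4 lower; 2 and 3 adjusted over the list alone), with Hk2 at 1.66 and Slc16a3 at -2.44, and the list median of -0.27 turned to 0.12 after median-of-ratios scaling, with 4 higher and 1 lower (2 and 1 after quantile normalization). Fibroblast genes fell in 4 and rose in 1 of 9 cases, led by Col1a1 (-2.98), and their median of -0.21 turned to 0.18 after median-of-ratios scaling. Endothelial genes fell in 3 and rose in 1 of 9 cases. Smooth muscle genes fell in 4 and rose in 1 of 9, a balance that turned with the scaling: 2 fell and 3 rose after median-of-ratios scaling, and 2 fell and 4 rose after quantile normalization. Erythroid genes rose in 4 of 7 cases, and neutrophil, epicardial, skeletal muscle and Schwann genes fell in 3, 3, 2 and 2 cases; the epicardial median of -0.39 turned to 0.02 under quantile normalization. Immediate early genes rose in 8 and fell in 6 of 21 cases, with Nr4a1 at 1.74 and Myc at -1.95. In the IL-4/IL-13 list 2 genes rose and 2 fell, its median of -0.05 turned to 0.34 after median-of-ratios scaling with 6 higher and 1 lower (5 and 0 after quantile normalization), and Retnla was listed at 0 in both P0 libraries. Both adult libraries held male-type expression (Xist at 0.164 and 0.0974 FPKM), while the P0 libraries held Xist at 29.8 and 39.5 FPKM, so sex and age differ together; both P7 libraries had Xist with little expression from the Y chromosome.

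**Figure D2:**
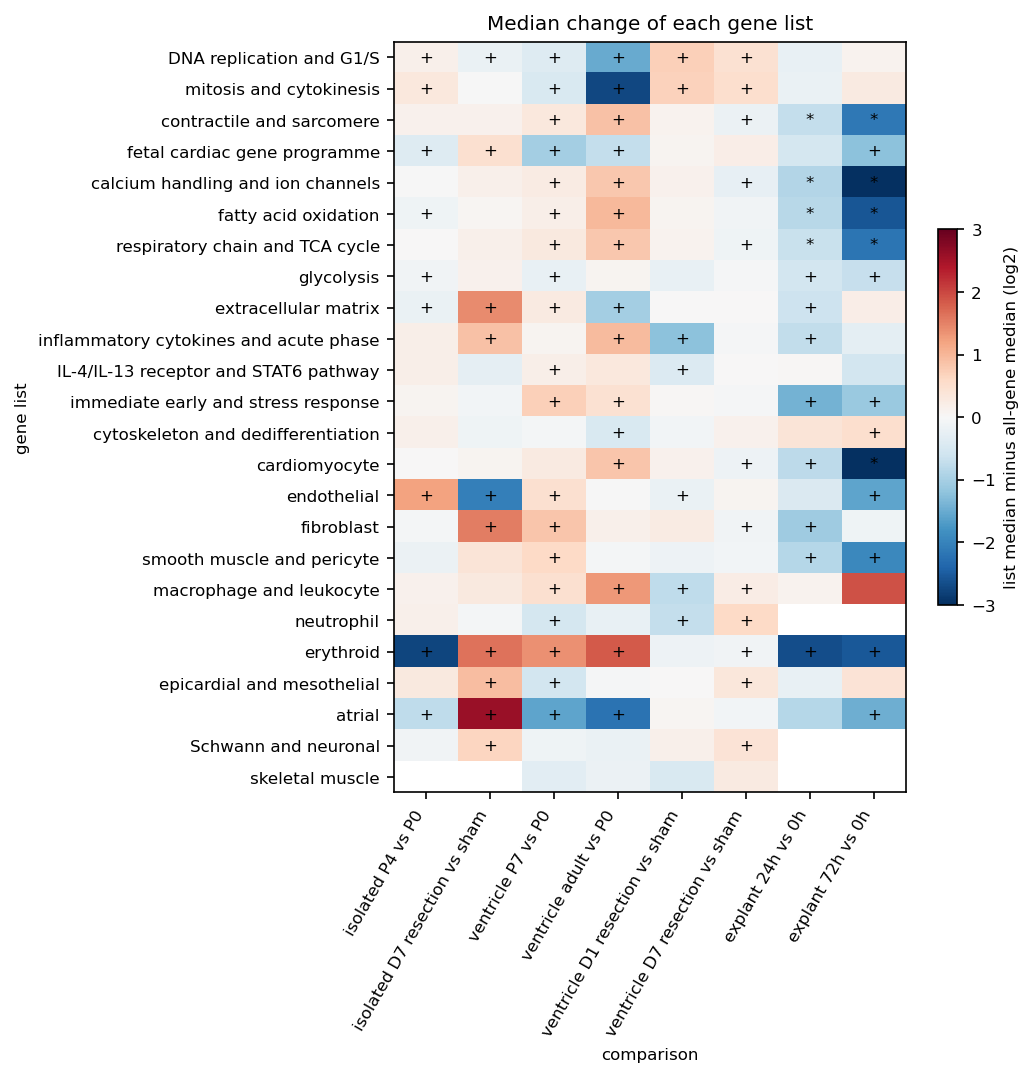
Median log2 fold change of each gene list minus the median of all genes tested, per comparison (colour, log2). A plus marks lists with an adjusted camera p under 0.05 at the preset correlation only, and a star those that also pass with an estimated correlation, which occur in the explant columns; white cells had too few tested genes.

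The comparison of isolated cardiomyocytes at P4 and P0 asked which genes change within the first days after birth. With n = 3 per group almost no gene passed the threshold. In set tests at the preset correlation the mitosis, replication and endothelial lists were higher at P4, and the erythroid, glycolysis, atrial, fetal, fatty acid and extracellular matrix lists lower (adjusted p = 0.0043, 0.0094, 0.019, 0.034 and 0.034 for the last 5), with 0 members called over all genes in each. None of these held with an estimated correlation (adjusted p = 0.399 for erythroid genes and 0.951 to 0.953 for the others) or with fry (adjusted p from 0.952 to 0.988). The fetal, atrial and matrix lists did not pass at the preset correlation under either other scaling, nor the fatty acid list after median-of-ratios scaling. Limma called 1 of 13080 genes, and 344 had an unadjusted p under 0.05. The count was 0 with the replicate number as a block and on the compared groups alone, and 11 in a single fit of all 36 libraries. Mapt, named after its value was seen, rose by 1.41 (adjusted p = 0.027). This call was lost without P0 replicate 1, P0 replicate 2, P4 replicate 1, P4 replicate 2 or P4 replicate 3, each of which left 0 genes, and without P0 replicate 3 the 1 gene called was lower. Ankrd1 was higher, at 417 ± 20.8 against 154 ± 25.1 FPKM (SD, n = 3), with an adjusted p of 0.073. Myh6, Myh7 and Tnni1 differed by -0.07, -0.08 and -0.11, and Nppb by 0.99, all with an adjusted p of 1.

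All 29 mitosis genes had a higher estimate at P4, with a median of 0.40 against 0.09 for all genes (adjusted p = 2.9e-10), but no gene passed singly, in all genes or adjusted over the list alone, and adjusted p = 0.951 with an estimated correlation. The estimates of Cenpa and Kif20a were 0.67 and 0.68 (both adjusted p = 1). The 27 replication genes had a median of 0.23 (adjusted p = 0.034; adjusted p = 0.953 with an estimated correlation). The 7 erythroid genes had a median of -2.66 (adjusted p = 1.75e-10; adjusted p = 0.399 with an estimated correlation), and 4 of them fell adjusted over the list alone. Globin FPKM summed to 20906, 20582 and 977 in the P0 libraries and to 371, 1085 and 1655 in the P4 libraries, so the difference rested on P0 replicates 1 and 2. The 9 endothelial genes were higher as a set (adjusted p = 0.0043; adjusted p = 0.951 with an estimated correlation), with Cdh5 at 41.5 ± 38.2 against 10.6 ± 12.9 FPKM (SD, n = 3). Atrial genes had a median of -0.68, and Myl7 ranged from 8.27 to 376 FPKM among the P4 libraries. In the fetal list 1 gene rose adjusted over the list alone; the others had 0 passing either way.

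The comparison of isolated cardiomyocytes 7 days after resection and sham asked which genes respond to injury in the muscle cells of a regenerating heart. Nearly all genes that passed were higher after resection. The largest changes were in lung epithelial and atrial genes, and single genes of other lists rose too. The extracellular matrix and fibroblast lists were higher in set tests at the preset correlation, with 2 of 22 and 0 of 9 genes passing singly, but not with an estimated correlation (adjusted p = 0.449 and 0.508) or with fry (adjusted p = 0.093 and 0.198). Genes of contraction, respiration and the cell cycle did not pass singly. The median of all genes was 0.13, and under the other scalings it was 0.00 and -0.01.

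Among 13080 genes 141 were higher and 2 lower. The surfactant gene Sftpc (ENSMUSG00000022097, chromosome 14, 70920747 to 70923888) had 495 ± 411 FPKM after resection and 0.862 ± 0.885 after sham (SD, n = 3), a change of 7.76 (adjusted p = 1.5e-05). Sftpb rose by 5.16, Sftpa1 by 4.47, Cxcl15 by 4.24 and the airway gene Scgb1a1 by 4.32. The atrial light chain gene Myl7 (ENSMUSG00000020469, chromosome 11, 5796639 to 5798785) rose by 5.78, from 3.67 ± 2.63 to 246 ± 125 FPKM (SD, n = 3, adjusted p = 0.012). Sln rose by 4.88, Myl4 by 4.40 and Nppa by 3.26, from 53.6 ± 25.3 to 495 ± 98.7 FPKM (SD, n = 3, adjusted p = 0.020). Of 8 atrial genes 5 rose, or 7 adjusted over the list alone (list median 2.72, adjusted p = 1.05e-09; adjusted p = 0.424 with an estimated correlation). Of 14 fetal genes 4 rose, or 6 adjusted over the list alone, and 3 of the 4, Myl7, Myl4 and Nppa, are in the atrial list; the other is Ankrd1. Without the lung and atrial list genes 119 passed, of untested origin.

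Extracellular matrix genes rose in 2 of 22 cases, Tnc (1.96) and Ctgf (1.00), and in 18 adjusted over the list alone, with a list median of 1.55 (adjusted p = 1.05e-09; adjusted p = 0.449 with an estimated correlation). Fibroblast markers passed in 0 of 9 cases and in 8 adjusted over the list alone, with Dpt at 2.01 and Col3a1 at 1.80 and a list median of 1.68 (adjusted p = 6.7e-05; adjusted p = 0.508 with an estimated correlation). Their mean level differed by 1.65 on the log2 scale (exact permutation p = 0.3, adjusted p = 0.36). Sham replicate 3, at 5.87, lay within the resected range of 5.38 to 6.67, and the other shams were at 3.27 and 3.48. Without sham replicate 3 the fibroblast median was 2.54 with 9 genes passing, and 19 matrix genes passed; without sham replicate 1, sham replicate 2 or resection replicate 3 no matrix gene passed, and without resection replicate 1 or 2 1 did. Endothelial markers had a median of -1.92 (adjusted p = 1.1e-08; adjusted p = 0.449 with an estimated correlation) and 0 of 9 passed either way. The mean endothelial level was 3.90 after resection and 5.75 after sham on the log2 scale (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow, adjusted p = 0.2). Il33 rose by 1.84 as the 1 inflammatory gene that passed (3 adjusted over the list alone), Krt8 by 2.44 among cytoskeleton genes (2 adjusted over the list alone) and Lyz2 by 2.45 among 3 leukocyte genes. In the Schwann list 3 of 3 genes rose adjusted over the list alone, and in the IL-4/IL-13 list 1 did. With fry atrial genes passed (adjusted p = 0.013). Erythroid and epicardial lists had medians of 1.77 and 1.06 with 0 genes passing. The fetal, inflammatory, erythroid, epicardial and Schwann lists were also higher as sets at the preset correlation (adjusted p = 0.0029, 0.031, 0.044, 0.031 and 0.035), and not with an estimated correlation (adjusted p = 0.449, 0.846, 0.704, 0.704 and 0.434); with fry the Schwann list passed (adjusted p = 0.0038). After quantile normalization the Schwann list did not pass (adjusted p = 0.052 at the preset correlation).

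Cell-cycle genes did not pass in isolated cells at day 7: Mki67 differed by -0.01 and Ccnb1 by 0.04, and 0 of 27 replication and 0 of 29 mitosis genes passed either way. Replication genes had a median of -0.06, below the median of all genes (adjusted p = 0.014; adjusted p = 0.911 with an estimated correlation). Myh6, Myh7, Tnni1 and Tnni3 differed by 0.17, 0.11, -0.30 and 0.29 (adjusted p from 0.71 to 0.91). Contractile, calcium, fatty acid, respiratory, glycolysis, immediate early, cardiomyocyte, smooth muscle and neutrophil lists had 0 genes passing either way. The count of 143 genes was 53 on the compared groups alone, 67 with the endothelial level as a covariate, 271 without the expression filter and 705 in a single fit of all 36 libraries. It rested on particular libraries: it was 28 without sham replicate 1, 25 without sham replicate 2, 57 without resection replicate 3 and 761 without sham replicate 3.

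**Figure D3:**
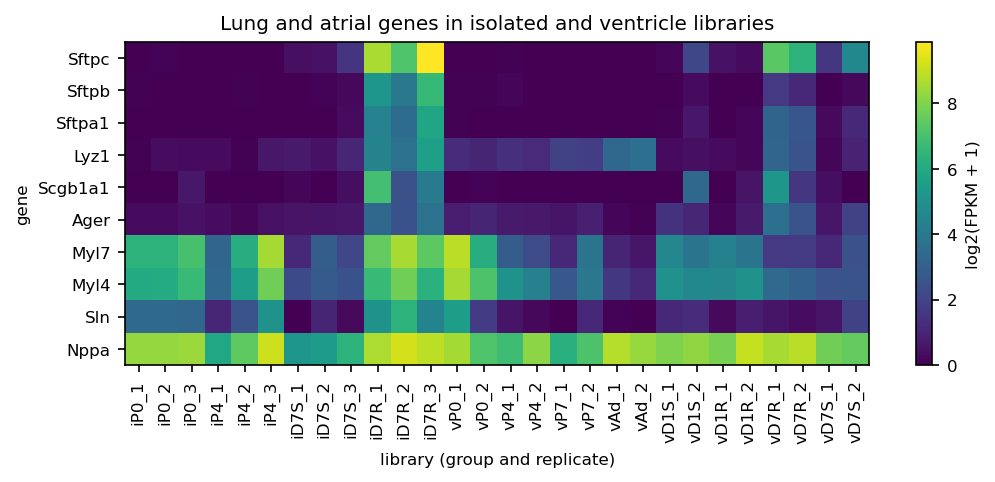
Level of lung genes (Sftpc to Ager) and atrial genes (Myl7 to Nppa) in each isolated (i) and ventricle (v) library as log2(FPKM + 1), with R for resection and S for sham. Sftpc stood at 142 to 947 FPKM in the isolated resected libraries and at 1.88 FPKM or less in their shams.

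The comparison of whole ventricle 1 day after resection and sham asked for the early response to injury. Of 16 inflammatory genes 15 and of 12 leukocyte genes 7 were lower after resection than after sham, while 8 of 28 replication and 8 of 29 mitosis genes were higher. As sets none of these held with an estimated correlation (adjusted p = 0.22 for inflammatory genes and 0.334 for the others), and the replication and mitosis lists did not pass with fry either (adjusted p = 0.058 and 0.067). The median of all genes was -0.16, and under the other scalings it was -0.01 and 0.02.

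Among 14201 genes 198 were higher and 1265 lower. The share of higher genes was 13.5%, against 41.5% after median-of-ratios scaling and 49.8% after quantile normalization. The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 53967367 to 53971046) fell by 3.40 (adjusted p = 4.6e-06). Ccl6 fell by 3.31, Ccl9 by 3.14, Lgals3 by 3.10, Arg1 by 2.95, Sprr1a by 2.91 and Mt2 by 2.77. Spp1 was at 10.1 ± 2.60 FPKM after resection and 95.3 ± 7.82 after sham (SD, n = 2), a change of -3.13. Of 16 inflammatory genes 15 were lower, or 16 adjusted over the list alone, with a median of -1.38 (adjusted p = 1.6e-14; adjusted p = 0.22 with an estimated correlation). Of 12 macrophage and leukocyte genes 7 were lower (9 adjusted over the list alone), with Tyrobp at -2.05 and Lyz2 at -1.71, and of 6 neutrophil genes 3 (5 adjusted over the list alone; 1 under either other scaling), with S100a8 at -1.91. In the IL-4/IL-13 list 5 genes were lower and 1 higher (8 and 1 adjusted over the list alone; 3 and 1 after median-of-ratios scaling, 2 and 1 after quantile normalization), among them Arg1, Chi3l3 (-1.24) and Il4ra (-0.82). The neutrophil, IL-4/IL-13 and endothelial lists were lower as sets at the preset correlation (each adjusted p = 0.012), and not with an estimated correlation (adjusted p = 0.771, 0.508 and 0.771); with fry the IL-4/IL-13 and endothelial lists passed (adjusted p = 0.0020 and 0.044).

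Of 28 replication genes 8 were higher after resection at day 1 and none lower, or 16 adjusted over the list alone, with Cdc6 at 1.03 and Uhrf1 at 0.80; after median-of-ratios scaling 17 were higher and after quantile normalization 18. Of 29 mitosis genes 8 were higher, or 16 adjusted over the list alone, with Prc1 at 1.08 and Mki67 at 1.02, from 8.83 ± 0.0934 to 18.9 ± 1.74 FPKM (SD, n = 2, adjusted p = 0.039); 15 and 11 mitosis genes were higher under those scalings. The list medians were 0.55 and 0.53 (both adjusted p = 1.3e-18; both adjusted p = 0.334 with an estimated correlation). With fry, which asks about each list without reference to other genes, they did not pass, while inflammatory and leukocyte genes did (adjusted p = 2.0e-04 and 0.004). Nr4a1 (1.40), the ion-channel subunit gene Kcnip2 (1.36) and Upp1 (1.19) were the named genes with large increases. Extracellular matrix genes were lower in 6 of 23 cases, with Timp1 at -2.15, and cytoskeleton genes in 5 of 20, with Cd44 at -1.35; the matrix list median of -0.13 turned to 0.05 under both other scalings, with 3 lower in each. Endothelial genes were lower in 3 of 9 cases, with Cldn5 at -0.83, smooth muscle genes in 3 of 9 (4 adjusted over the list alone; for both lists 2 after median-of-ratios scaling and 1 after quantile normalization) and glycolysis genes in 3 of 16 (5 adjusted over the list alone). The glycolysis median was -0.37 (adjusted p = 0.088 as a set); after quantile normalization it was -0.18 with 1 gene lower, and the set passed (adjusted p = 0.0388). Immediate early genes were lower in 4 cases and higher in 1 of 21 (5 and 2 adjusted over the list alone), with Hmox1 at -2.07. Fetal genes were lower in 2 of 14 cases, Actn1 (-1.12) and Slc2a1 (-1.01), or 3 adjusted over the list alone. Contractile, calcium, fatty acid and respiratory lists had 1, 2, 1 and 1 genes passing; of calcium genes 1 was higher and 1 lower, and 3 were higher after median-of-ratios scaling. Myh6, Myh7, Tnni1 and Nppa differed by 0.09, 0.34, -0.32 and 0.32 without passing. Erythroid and epicardial lists had 1 gene lower each (3 and 1 adjusted over the list alone), the skeletal muscle list 1 adjusted over the list alone, and cardiomyocyte, fibroblast, atrial and Schwann lists had 0, while 2 fibroblast genes were higher under either other scaling. The count of 1463 genes was 202 on the 8 surgery libraries of ventricle alone, 19 on the compared groups alone, 516 in a single fit of all 36 libraries and 806 after quantile normalization. It was 796 without sham replicate 1, 217 without sham replicate 2, 483 without resection replicate 1 and 3034 without resection replicate 2.

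At day 7 the same comparison of whole ventricle asked what persists once the early response has passed. Few genes passed singly, and none did in a fit on the surgery libraries alone. The replication, mitosis, leukocyte and neutrophil lists were higher in set tests at the preset correlation, with 0 members called over all genes in each. None of these held with an estimated correlation (adjusted p = 0.458, 0.458, 0.479 and 0.479) or with fry (adjusted p = 0.118, 0.135, 0.135 and 0.189). The median of all genes was 0.11, and under the other scalings it was 0.00 and -0.01. Among 14201 genes 22 were higher and 1 lower, while 1547 had an unadjusted p under 0.05. The count of 23 was 0 on the 8 surgery libraries alone, 1 with a pseudocount of 0.1, 2 on the compared groups alone, 14 after quantile normalization and 77 without the expression filter. Of the 23 genes 7 are in the lung list. Spp1 (ENSMUSG00000029304, chromosome 5, 104864136 to 104870069) rose by 2.31, from 3.43 ± 2.89 to 18.6 ± 3.33 FPKM (SD, n = 2, adjusted p = 0.016). Lyz1 rose by 2.32, Sftpa1 by 2.24, Enpp2 by 1.54, C1qtnf3 by 1.47, Saa3 by 1.37 and Il33 by 0.99. On the surgery libraries alone Spp1 and Saa3 no longer passed (adjusted p = 0.30 and 0.324), nor with the pseudocount of 0.1 (both adjusted p = 0.106) or on the compared groups alone (both adjusted p = 0.268). Saa3 also failed to pass after either other scaling and in a single fit of all 36 libraries. Sftpc stood at 164 and 83.2 FPKM after resection and at 1.99 and 23.5 FPKM after sham. The count of 23 genes was 5 without resection replicate 1, 13 without resection replicate 2 and 44 without sham replicate 2. Sex differed between the samples as well: resection replicate 2 held male-type expression (Xist at 0.11 and Ddx3y at 32.9 FPKM) and sham replicate 1 female-type expression (Xist at 58.6 and Ddx3y at 0.0193 FPKM), while resection replicate 1 (23.0 and 23.2 FPKM) and sham replicate 2 (35.9 and 12.6 FPKM) held both.

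Of 28 replication genes 0 passed over all genes and 13 rose adjusted over the list alone, with a median of 0.56 (adjusted p = 1.0e-12 at the preset correlation). Of 29 mitosis genes 0 passed and 16 rose adjusted over the list alone, with a median of 0.62 (adjusted p = 1.1e-12 at the preset correlation). Uhrf1 was at 9.87 ± 0.154 against 5.08 ± 0.170 FPKM (SD, n = 2, adjusted p = 0.066) and Mki67 differed by 0.62 (adjusted p = 0.45). Calcium handling genes had a median of -0.13, below that of all genes (adjusted p = 1.9e-05; adjusted p = 0.458 with an estimated correlation), with 0 of 22 passing either way. Contractile genes had a median of -0.08 and respiratory genes of -0.03, with 0 passing either way. As sets the contractile, respiratory, cardiomyocyte, fibroblast and erythroid lists were lower and the epicardial and Schwann lists higher at the preset correlation (adjusted p from 8.2e-04 to 0.040), and none with an estimated correlation (adjusted p from 0.404 to 0.605). With fry the Schwann list passed (adjusted p = 0.027). After quantile normalization the contractile, cardiomyocyte, fibroblast and erythroid lists did not pass. Neutrophil genes rose in 4 of 6 cases and macrophage genes in 2 of 12 adjusted over the list alone, with 0 over all genes in each and medians of 0.71 and 0.33 (adjusted p = 0.0023 and 0.0025 at the preset correlation). Inflammatory genes rose in 2 of 16 cases, Saa3 and Il33 (2 adjusted over the list alone; 0 over all genes under either other scaling), and matrix genes in 1, Spp1 (3 adjusted over the list alone). In the fetal, cytoskeleton, immediate early, IL-4/IL-13, epicardial and skeletal muscle lists 1 gene each rose adjusted over the list alone, and in the Schwann list 2 did. Fatty acid, glycolysis, cardiomyocyte, endothelial, fibroblast, smooth muscle, erythroid and atrial lists had 0 genes passing either way. Nppa was at 426 ± 62.0 against 197 ± 20.9 FPKM (SD, n = 2, adjusted p = 0.45), and Myh7 differed by 0.53 (adjusted p = 0.36).

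The explant series asked how adult cardiomyocytes change once they are taken out of the heart. Within 24 h the list of immediate early and stress response genes was lower as a set at the preset correlation, though not with an estimated correlation (adjusted p = 0.077), while single genes such as Gdf15 and Trib3 rose. By 72 h most genes of calcium handling, fatty acid oxidation and respiration had fallen, as had 11 of 19 contractile genes, while 1 contractile gene had risen. Of 18 cytoskeleton genes 14 had risen, or 8 and 9 under the other scalings. The median of all genes moved by 0.37 at 24 h and 0.76 at 72 h, and after median-of-ratios scaling by 0.00 and 0.08.

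At 24 h 1890 genes were higher and 317 lower among 12181. The share of higher genes was 85.6%, against 41.7% after median-of-ratios scaling and 46.8% after quantile normalization. Deviations of samples that share a replicate number correlated across groups, at 0.38 to 0.62 across genes, and with that number as a block 4125 genes were higher and 795 lower. The stress cytokine gene Gdf15 (ENSMUSG00000038508, chromosome 8, 73153291 to 73156355) rose by 6.61, from 3.42 ± 1.11 to 481 ± 322 FPKM (SD, n = 2, adjusted p = 0.0027). Plk2, Mthfd2, Trib3, Srxn1 and Atf5 rose by 4.62, 4.59, 4.39, 4.15 and 3.77. Fos (ENSMUSG00000021250, chromosome 12, 86814839 to 86818223) fell by 5.16, from 227 ± 22.2 to 5.43 ± 1.17 FPKM (SD, n = 2), Fosb by 4.28, Egr1 by 3.13 and Socs3 by 3.17. Immediate early and stress response genes fell in 10 and rose in 1 of 23 cases (12 and 3 adjusted over the list alone; adjusted p = 1.7e-10 as a set, and adjusted p = 0.077 with an estimated correlation). The count of 2207 genes was 1035 after quantile normalization, 1061 without the expression filter, 1109 on the compared groups alone and 4707 in a single fit of all 36 libraries. It was 242 without 0 h replicate 1, 276 without 0 h replicate 2, 56 without 24 h replicate 1 and 109 without 24 h replicate 2.

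In the metabolic and contractile lists few genes passed singly at 24 h. Fatty acid oxidation genes fell in 5 of 27 cases (6 adjusted over the list alone), with Pdk4 at -2.40, and 13 fell after median-of-ratios scaling. Their median was -0.47 (adjusted p = 1.2e-12; 0.047 with an estimated correlation). Calcium handling genes fell in 5 and rose in 1 of 22 cases, with Kcnj11 at -2.08 and Pln at -1.51, and 9 fell after median-of-ratios scaling. Contractile genes fell in 3 and rose in 1 of 19 cases, with Tcap at -1.46 and Actc1 at -1.38; their median of -0.35 turned to 0.05 under quantile normalization, where 0 passed and the set call was lost (adjusted p = 0.914). Respiratory genes had a median of -0.31 with 0 of 36 passing either way; 8 fell with the block and 10 after median-of-ratios scaling, while the set call was lost under quantile normalization (adjusted p = 0.488). Cytoskeleton genes rose in 6 and fell in 1 of 18 cases (7 and 1 adjusted over the list alone), with Cd44 at 2.39, and in 3 under either other scaling. Inflammatory genes rose in 3 and fell in 3 of 10, with Csf1 at 2.55; as a set they were lower (adjusted p = 0.037), which the block ended (adjusted p = 0.053) and which had adjusted p = 0.225 with an estimated correlation. Fetal genes rose in 1 and fell in 2 of 11 (2 and 2 adjusted over the list alone), with Slc2a1 at 1.32 and Acta2 at -3.60. Timp1 rose by 2.33 as the 1 matrix gene that passed; 3 others fell after median-of-ratios scaling, and 2 fell with 0 higher after quantile normalization. Of 16 glycolysis genes 1 rose, Slc2a1, while 5 fell after median-of-ratios scaling and 1 after quantile normalization with 0 higher in each. Cardiomyocyte markers fell in 1 of 7 cases, and their median of -0.41 turned to 0.21 under quantile normalization. Myl7 was listed at 0 in both 24 h libraries. Dcn, Rgs5 (-2.20) and Hbb-b2 (-2.41), 1 gene each of the fibroblast, smooth muscle and erythroid lists, fell; adjusted over the list alone 3, 2 and 2 genes did. Replication, mitosis, IL-4/IL-13, endothelial, leukocyte and epicardial lists had 0 genes passing either way.

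At 72 h 5718 genes were higher and 1109 lower than at 0 h. The share of higher genes was 83.8%, against 46.4% after median-of-ratios scaling, and after quantile normalization 2055 genes were higher and 2051 lower. Actc1 fell by 5.57, from 5908 ± 870 to 124 ± 25.9 FPKM (SD, n = 2, adjusted p = 4.5e-05), Tcap by 5.67, Kcnip2 by 5.46, Asb2 by 5.97, Myh7 by 4.25 and Tnni3 by 3.64. Myh6 was listed at 0 in 0 h replicate 2 beside 4762 FPKM in replicate 1. Its estimate of 1.39 did not pass (adjusted p = 0.72), and with that value left out it fell by 4.71 (adjusted p = 2.8e-04). Gdf15 rose by 7.40, the detoxification genes Gsta1 and Gsta2 by 7.13 and 6.74, Asns by 5.79 and Hmox1 by 5.18.

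Respiratory genes fell in 32 of 36 cases by 72 h (33 adjusted over the list alone), with Idh2 at -2.25. Fatty acid oxidation genes fell in 24 of 27 (25 adjusted over the list alone), with Pdk4 at -4.18. Calcium handling genes fell in 18 of 22, with Srl at -4.23, contractile genes fell in 11 and rose in 1 of 19, and cardiomyocyte markers fell in 6 of 7, with Myl2 at -3.74. These lists passed as sets with an estimated correlation as well (adjusted p of 0.0068, 0.013, 0.0068, 0.0086 and 0.014 in that order). Cytoskeleton genes rose in 14 of 18 cases, with Msn at 3.39 and Cd44 at 3.65 (adjusted p = 0.0092 as a set, and adjusted p = 0.135 with an estimated correlation). Extracellular matrix genes rose in 10 of 16 cases (5 under either other scaling), with Timp1 at 4.02, and Spp1 was listed at 0 in both 0 h libraries and at 31.1 ± 28.6 FPKM (SD, n = 2) at 72 h. Replication genes rose in 8 of 17 cases, with Prim1 at 1.76, and mitosis genes rose in 5 and fell in 1 of 7, with Top2a at 1.53 and Cenpa at -3.01. After median-of-ratios scaling 3 of each rose, and after quantile normalization 2 of each. With fry both lists passed (adjusted p = 0.0031 and 0.0029), though not against other genes (adjusted p = 0.519 and 0.731). Immediate early genes rose in 7 and fell in 9 of 23, with Fos at -6.08, against 2 and 13 after median-of-ratios scaling and 3 and 10 after quantile normalization. Fetal genes rose in 3 and fell in 3 of 11, against 1 and 5 after median-of-ratios scaling and 2 and 4 after quantile normalization. Slc2a1 rose by 3.61 and Tpi1 fell by 1.78 among glycolysis genes, of which 4 rose and 3 fell; the set was lower (adjusted p = 0.044), which the block ended (adjusted p = 0.071) and which had adjusted p = 0.156 with an estimated correlation, and its median of 0.06 turned to -0.71 after median-of-ratios scaling, with 1 higher and 7 lower (2 and 5 after quantile normalization).

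Among the remaining lists at 72 h, inflammatory genes rose in 3 and fell in 3 of 10 cases, with Osmr at 3.64 and Socs3 at -3.78. IL-4/IL-13 genes rose in 3 and fell in 1 of 7, with Il4ra at 1.18, and their median of 0.22 turned to -0.63 after median-of-ratios scaling, with 0 higher and 3 lower (0 and 1 after quantile normalization). Macrophage genes rose in 3 of 3 cases, with Cd68 at 5.81, from 0.739 ± 0.482 to 98.6 ± 39.7 FPKM (SD, n = 2), and Csf1r at 2.66. Fibroblast genes rose in 3 of 6 cases, while 2 fell and 0 rose under either other scaling. Epicardial genes rose in 6 of 7 cases (7 adjusted over the list alone), or in 2 and 3 under the other scalings. Endothelial genes fell in 4 of 9 cases (3 adjusted over the list alone; 7 under either other scaling), with Cdh5 at -1.96, smooth muscle genes in 2 of 4, atrial genes in 2 of 4 and erythroid genes in 1 of 2.

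Whether injury or culture turned back the postnatal programme was asked with the 1907 genes that rose and the 6219 that fell from P0 to the adult ventricle. In explants at 72 h the genes that had risen postnatally had a median of -0.38 and those that had fallen a median of 1.04, against 0.76 for all genes. The set tests passed in both directions (adjusted p = 6.5e-33 and 8.6e-10), though not with an estimated correlation (adjusted p = 0.088 and 0.171). Of 4147 genes called in both comparisons 3746 changed in opposite directions. Among these 3192 fell postnatally and rose in culture, where 2420 were expected from the margins, and 554 rose postnatally and fell in culture, where 154 were expected. The correlation across 11811 genes was -0.38 (Pearson r, and Spearman rho -0.38), and genes are not independent replicates.

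After resection the medians of these sets lay closer to that of all genes. In whole ventricle at day 7 the genes that had risen postnatally had a median of 0.01 and those that had fallen of 0.16, against 0.11 for all genes (adjusted p = 3.9e-08 and 6.1e-07; adjusted p = 0.171 for both with an estimated correlation), and r across genes was -0.23. At day 1 neither set passed (adjusted p = 0.17 and 0.52), and r was -0.06. In isolated cells at day 7 the direction was the opposite, with medians of 0.24 and 0.09 against 0.13 for all genes (adjusted p = 0.0043 and 0.023; adjusted p = 0.803 for both with an estimated correlation). Without resection replicate 3 these medians were 0.08 and 0.09, and r across genes turned from 0.08 to -0.04. The rising set no longer passed without sham replicate 3 (0.34), and the falling set without sham replicate 3 (0.22), resection replicate 1 (0.14) or ventricle P0 replicate 2 (0.089); without the latter the rising set newly passed at day 1 in ventricle (-0.084). The change from P0 to P4 and the resection effect in isolated cells had r = -0.37 (Spearman rho -0.21) across 13080 genes. It was -0.17 without P4 replicate 3 and -0.50 without P4 replicate 2. Erythroid medians were -2.66 and 1.77 and atrial ones -0.68 and 2.72, the first of which turned to 0.32 without P4 replicate 1. Other cell-type lists lay on the same side in both, with epicardial medians of 0.38 and 1.06, macrophage medians of 0.23 and 0.42 and fibroblast medians of 0.03 and 1.68. Their share of r was not tested. The same P0 and adult libraries define both sets, so these tests share their errors.

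Resection effects at day 7 and day 1 in ventricle were compared directly, with day 1 labels as given. The effect was higher at day 7 for 804 genes and lower for 35 (55 genes in all on the surgery libraries alone), with 95.8% higher, against 75.4% after median-of-ratios scaling and 72.9% after quantile normalization, and the median of all genes was 0.27. Inflammatory genes differed in 9 of 16 cases (16 adjusted over the list alone), with Saa3 at 4.77, and macrophage genes in 6 of 12 (11 adjusted over the list alone; 3 and 2 under the other scalings), with Tyrobp at 2.97; as sets their adjusted p values were 1.05e-12 and 1.9e-06, and adjusted p = 0.282 and 0.431 with an estimated correlation. Neutrophil genes differed in 3 of 6 cases (5 adjusted over the list alone), matrix genes in 5 of 23 (7 adjusted over the list alone), cytoskeleton genes in 5 of 20 (6 adjusted over the list alone) and IL-4/IL-13 genes in 2 of 12 (7 adjusted over the list alone). Replication and mitosis genes differed in 0 cases either way. At the preset correlation the neutrophil, IL-4/IL-13, cytoskeleton and endothelial lists were higher as sets, and the replication, mitosis, contractile, calcium, fatty acid, respiratory, cardiomyocyte and fibroblast lists lower (adjusted p from 5.0e-04 to 0.045); none held with an estimated correlation (adjusted p from 0.483 to 0.631). The contractile, fatty acid and cardiomyocyte lists did not pass after quantile normalization, nor the cytoskeleton list after median-of-ratios scaling. All 6 genes called at both times were lower at day 1 and higher at day 7, where 1.96 were expected. The count of 839 was 184 without day 1 sham replicate 2, 464 without day 1 resection replicate 1, 2662 without day 1 resection replicate 2, 240 without day 7 resection replicate 1, 334 without day 7 sham replicate 1 and 508 without day 7 sham replicate 2.

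The resection effect at day 7 was also compared between isolated cells and whole ventricle. The effect differed for 12 of 14834 genes, 6 higher and 6 lower in isolated cells, with 84.9% higher after median-of-ratios scaling and 83.7% after quantile normalization. The surfactant gene Sftpb differed by 3.87 and Napsa by 1.92. Atrial genes had a median difference of 2.19 (adjusted p = 6.0e-10; adjusted p = 0.091 with an estimated correlation), with 0 of 8 passing and 7 adjusted over the list alone. Of fibroblast genes 6 of 9 differed adjusted over the list alone, with 0 over all genes. Replication genes had a median difference of -0.65 (adjusted p = 6.0e-10; adjusted p = 0.461 with an estimated correlation) with 0 of 28 passing either way. At the preset correlation the mitosis and endothelial lists were lower as sets too, and the contractile, fetal, calcium, respiratory, glycolysis, matrix, fibroblast and erythroid lists higher (adjusted p from 1.9e-08 to 0.039); none held with an estimated correlation (adjusted p from 0.461 to 0.616) or with fry (adjusted p from 0.361 to 0.529). The contractile, fetal, respiratory and glycolysis lists did not pass after quantile normalization, nor the glycolysis list after median-of-ratios scaling. The 12 genes called at day 7 in both preparations were higher after resection in both, where 0.145 were expected. Of these 7 are in the lung list (Sftpb, Sftpa1, Sftpd, Slc34a2, Cxcl15, Lyz1 and Cldn18), and the other 5, named after their values were seen, were Cxcl13, Enpp2, Il33, Slc27a6 and Wfdc2. Whether the other 5 share a source with the lung genes was not tested. On the compared groups alone 7 genes differed. The count of 12 ranged from 5 without isolated sham replicate 1 to 205 without isolated sham replicate 3. It was 6 without isolated sham replicate 2, 79 and 111 without isolated resection replicates 1 and 2, 6 and 19 without ventricle resection replicates 1 and 2, and 25 and 19 without ventricle sham replicates 1 and 2.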

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

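The tests on the 9 further lung genes without the expression filter, on induced lung genes, on the return of fetal genes, and on the day 1 labels, leukocytes and scaling were chosen only after the results they concern were seen. A tested difference between the effects of resection in 2 groups of samples singled out the results here; groups held 2 or 3 samples, so single samples were not tested as outliers.

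The resection effect in ventricle differed between day 7 and day 1 for 839 genes, as exchanged day 1 labels could also give. Among the named genes with a higher effect at day 7 were Spp1 (5.44), Saa3 (4.77), Ccl6 (4.57), Sftpc (4.51), Lgals3 (4.32), Ccl9 (4.09), Mt2 (3.55) and S100a8 (3.36), as differences of log2 changes. Kcnip2 (-1.48), Art1 (-1.40), Rnaset2b (-1.35), Pdzd9 (-1.28), Apln (-1.15), Oxct1 (-1.14), Vtn (-1.08) and Ckmt2 (-1.02) had a lower effect. The day 7 effect differed between isolated cells and ventricle for 12 genes, among them Sftpb (3.87) and Napsa (1.92), both higher in the former.

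Lung epithelial genes were higher in isolated cells after resection, with 19 of 21 tested genes of the lung list called, all higher. Of the 9 lung genes not looked at when they were listed, 4 passed the expression filter, which Cyp2f2 and Cdh1 reached through their resected libraries, so all 9 were compared without that filter. Their median change was 0.71, outside the range of -0.05 to 0.22 of random lists of similar expression, with 1 called (Cdh1, at 1.56). The lowest were Marco (0.15), Foxj1 (0.20) and Ear1 (0.21), each under 0.5 FPKM in every isolated library of day 7. Lung tissue carried into the resected samples is a candidate these genes do not settle. Sftpc stood at 396, 142 and 947 FPKM and Scgb1a1 at 121, 4.45 and 16.5 in resected libraries. Of the 27 genes in the lung list 18 had been seen in these libraries first, 2 had a mean of at least 1 FPKM in isolated sham cells and 5 in sham ventricle, and 1 is in another list. Induction of lung genes in heart cells stays open: the highest sham ventricle at day 7 held 23.5 FPKM of Sftpc, below the lowest resected value of 83.2. Lung genes appeared in libraries labelled sham. Scgb3a2 stood at 3.10 FPKM in ventricle sham replicate 1 at day 7, above both resected ventricles (2.47 and 2.51). Day 1 sham replicate 2 held 14.5 FPKM of Scgb3a2, 8.85 of Scgb1a1 and 3.27 of Sftpc. The ratio of Sftpc to Sftpb was 9.75 to 11.0 in isolated and 67.8 and 76.3 in ventricle resected libraries, with the cause untested.

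Atrial genes were higher in isolated cells after resection. Of 6 further atrial genes not looked at before, all were tested, and their median was 0.87, outside the range of -0.11 to 0.36 of random lists; 1 was called, and 4 had at least 1 FPKM in sham cells, while 1 is in another list. More atrial cells in the resected isolations are a candidate these genes do not settle. Of them Pam, Kcnk3 and Kcnj5 held at least 26.6 FPKM in sham ventricles at day 7. In whole ventricle at day 7 the further atrial genes had a median of 0.03. A return of fetal genes in ventricular cardiomyocytes stays open. Myl7, Myl4, Sln and Stard10, picked as called in isolated cells, had medians of 4.64 there (interquartile range 1.44) and -0.26 in whole ventricle (0.55). In resected ventricles at day 7 Myl7, Sln, Myl4 and Stard10 reached at most 2.19, 0.485, 9.33 and 2.96 FPKM. Resected isolated libraries held at least 167, 21.1, 78.1 and 17.9. Over all 7 atrial list genes other than Nppa the medians were 2.17 (interquartile range 2.83) and -0.06, which leaves the rest open. Nppa does not decide. It changed by 1.11 in ventricle (adjusted p = 0.45), and its 382 and 469.8 FPKM in resected ventricles overlapped the isolated values.

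Inflammatory genes were lower after resection than after sham in ventricle at day 1, with a median of -1.38. Scaling of the authors' values is argued against, since after median-of-ratios scaling the median was -1.23 (adjusted p = 1.5e-16). An exchange of the sham and resected labels at day 1 cannot be told apart from a true difference: the mitosis median was 0.53 as labelled, with 8 of 29 genes called, and 0.62 at day 7, with 0 called, but the inflammatory median at day 7 was 0.07 with an interquartile range of 0.57. Fewer leukocytes in the resected samples likewise stay open, as the macrophage and leukocyte list had a median of -0.91 and an interquartile range of 0.75, which reaches that of the inflammatory list. Its members moved unequally. Tyrobp (-2.05), Lyz2 (-1.71), Cd68 (-1.30), Fcer1g (-1.27), Emr1 (-0.97), Cd163 (-0.94) and Ptprc (-0.89) were called lower, and C1qa (-0.57), C1qb (-0.56), Mrc1 (-0.43), C1qc (-0.34) and Csf1r (-0.30) were not called. Whether all leukocytes or some kinds of them were fewer stays open. A real difference between the operations at day 1 stays among the open explanations, and was not tested.

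For the count of 1 gene in isolated cells at P4 against P0, 2 of the 10 splits of the 6 samples into 3 and 3 gave as many genes, and the highest other split gave 2. For the 143 genes after resection at day 7, 1 of the 10 splits gave as many, the real one, and the highest other split gave 43. With 10 splits a share under 0.05 cannot be reached.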

How the results depend on the processing

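The settings for single values of 0, for the ventricle age or surgery libraries alone, for the endothelial covariate and for the removal of lung and atrial genes were chosen after seeing the data; the others were set before. Why a setting moved a result was not tested unless stated. Across the summary results 336 alternatives gave the same direction and call or a count within 1.5 times, 86 moved, 14 no longer passed, 2 newly passed and 5 reversed. For gene lists 3003 stayed, 338 no longer passed, 126 newly passed and 18 reversed; for named genes the numbers were 8781, 753, 111 and 3. Of the marker levels 184 moved and 200 stayed.

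Without the expression filter 6 genes were called in isolated cells at P4, 271 in isolated cells at day 7, 77 in ventricle at day 7, 1061 in explants at 24 h and 127 for the difference between preparations. With a pseudocount of 0.1 ventricle at day 7 had 1 gene. After median-of-ratios scaling the counts were 3 at P4, 4324 in explants at 72 h, 313 for day 7 against day 1 and 53 between preparations. Quantile normalization gave 4 at P4, 806 in ventricle at day 1, 14 at day 7, 1035 and 4106 in explants at 24 and 72 h, 207 for day 7 against day 1 and 43 between preparations. With the replicate number as a block P4 had 0 genes and explants at 24 h had 4920.

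A single fit of all 36 libraries gave 11 genes at P4, 705 in isolated cells at day 7, 482 in ventricle at P7, 516 at day 1, 4707 in explants at 24 h and 294 for day 7 against day 1. Fits on the compared groups alone, which leave fewer samples to estimate the spread, gave 0 at P4, 53 in isolated cells at day 7, 19 and 2 in ventricle at day 1 and day 7, 1109 in explants at 24 h, 55 for day 7 against day 1 and 7 between preparations. On the surgery libraries of ventricle alone the counts were 202 at day 1, 0 at day 7 and 55 for the difference. A 2-fold minimum left 432 genes at P7, 2920 in the adult, 361 at day 1 and 538 for day 7 against day 1. With the endothelial covariate 67 genes were called in isolated cells at day 7. Without lung and atrial list genes the counts were 119 in isolated cells and 16 in ventricle at day 7.

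Genes that fell postnatally had a median of 0.077 without the filter, -0.053 after median-of-ratios scaling, -0.052 after quantile normalization and 0.091 in the single fit in isolated cells at day 7, and no longer passed (adjusted p from 0.202 to 0.554). In ventricle at day 1 they newly passed after median-of-ratios scaling, at 0.023 (adjusted p = 0.024). With an estimated correlation the sets no longer passed in explants at 72 h (-0.38 and 1.04), isolated cells at day 7 (0.24 and 0.087) or ventricle at day 7 (0.014 and 0.16), and 9 of 97 pathway list tests still passed. A maturation set from isolated cells at P4 has 1 gene and gave no value for ventricle or explants. For isolated cells the set from ventricle at P7 against P0 reversed the direction at day 7, at 0.18 (adjusted p = 0.211) and 0.15 (adjusted p = 0.16). The correlation of the adult change with explants at 72 h was -0.34 without the filter, -0.42 after median-of-ratios scaling, -0.34 after quantile normalization and -0.31 in the single fit. With ventricle at day 1 it was -0.0074 without the filter, and at day 7 it was -0.15 with a pseudocount of 0.1 and -0.29 on the compared groups alone.

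Leaving out each replicate in turn gave 0 to 1 genes at P4, 25 to 761 in isolated cells at day 7, 581 to 1347 at P7, 6356 to 7044 in the adult, 217 to 3034 at day 1, 5 to 44 at day 7, 56 to 276 in explants at 24 h, 5000 to 5931 at 72 h, 184 to 2662 for day 7 against day 1 and 5 to 205 between preparations. Where this leaves a group with 1 sample, the lone sample is assumed to vary like the other groups. Medians of the genes that rose and fell postnatally ranged from -0.46 to -0.24 and from 0.99 to 1.07 in explants at 72 h, 0.077 to 0.38 and 0.0088 to 0.22 in isolated cells at day 7, -0.17 to -0.050 and -0.17 to -0.11 at day 1, and -0.03 to 0.06 and 0.12 to 0.19 at day 7. Correlations with the adult change ranged from -0.39 to -0.35 for explants, -0.042 to 0.15 for isolated cells, -0.09 to -0.04 at day 1 and -0.23 to -0.18 at day 7, and that of P4 with day 7 in isolated cells from -0.50 to -0.17. Pathway list tests numbered 92 to 103.

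Some results reversed. Without resection replicate 3 the maturation medians in isolated cells at day 7 were 0.077 and 0.094, and the correlation -0.042. In the single fit endothelial genes were at -0.36 at day 1 and 0.60 for day 7 against day 1, turned in the set test. At P4 leaving out P4 replicate 1 turned extracellular matrix (range over replicates -0.40 to 0.25) and atrial genes (-1.37 to 0.32), and leaving out P4 replicate 3 turned replication (0.046 to 0.53), fatty acid oxidation (-0.24 to 0.19) and immediate early genes (-0.016 to 0.43). In isolated cells at day 7 fatty acid oxidation (-0.13 to 0.50) turned without resection replicate 2 and respiration (0.0066 to 0.64) without resection replicate 3. The erythroid list for day 7 against day 1 (-0.40 to 1.07) turned without day 1 sham replicate 1. The endothelial covariate turned fatty acid oxidation (0.21), immediate early (-0.081) and endothelial genes (0.11) at P4, and contractile (-0.040), calcium (0.016), respiratory (-0.027), cardiomyocyte (-0.10) and erythroid genes (0.21) at day 7. Myh6 in explants reversed to -1.54 at 24 h (adjusted p = 0.024) with its single 0 treated as missing, and to -4.71 at 72 h both then (adjusted p = 2.8e-04) and without 0 h replicate 2; without 0 h replicate 1, which leaves the value of 0, it was 7.50. Depth is unknown from FPKM, so its limit on low genes was not measured.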

Other observations

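Ventricle at P4 and explants at 48 h entered no comparison. Tnni1 was at 639.6 ± 29.3 FPKM (SD, n = 2) in ventricle at P4, between 1199 ± 117 at P0 and 182 ± 61.8 at P7. In explants at 48 h Cd68 was at 28.3 ± 13.6 FPKM (SD, n = 2), against 2.76 at 24 h and 98.6 ± 39.7 at 72 h, and Myh6 was at 367 and 525 FPKM. Not all levels lay between those of the neighbouring groups: the mean endothelial marker level in explants was 1.13 on the log2 scale at 48 h, against 2.41 at 24 h and 1.38 at 72 h, and the macrophage level in ventricle was 2.18 at P4, against 2.22 at P0 and 2.61 at P7.

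Genes of the erythrocyte varied by library in isolated cells. Globin FPKM summed to 71555 in resection replicate 3 at day 7, against 10143 and 4894 in the other resected libraries. In the isolated P0 libraries the sums were 20906, 20582 and 977.

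Libraries of the ventricle age groups and of the ventricle surgery groups correlated less with each other (median r 0.863) than within each kind (0.966 and 0.973), while the age libraries correlated with the isolated libraries at 0.932. The labels name more than a single library protocol and sequencer but not which library had which, so each ventricle comparison set libraries of 1 kind against each other. The fits drew on all 16 ventricle libraries of both kinds for the spread between replicates, and on all 36 libraries for the difference between preparations. On the 8 surgery libraries alone the counts were 202 at day 1 and 0 at day 7. Correlations across genes do not count genes as independent replicates.

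Single values of 0 occurred in genes abundant in other libraries, such as Myh6 in explant 0 h replicate 2 and Col4a1 and Col4a2 in isolated P0 replicate 1. Sex differed between groups and within them. Explant libraries and adult ventricle had Y-linked expression with little Xist, with Ddx3y at 34.6 and 25.1 FPKM in the adult, and both P7 ventricles had Xist at 75.5 and 83.1 FPKM. In ventricle at day 7 Ddx3y was at 23.2 and 32.9 FPKM after resection and at 0.0193 and 12.6 FPKM after sham, with Xist at 23.0 and 0.11 and at 58.6 and 35.9 FPKM, so sex and resection are not separated there. At day 1 sham replicate 1 and resection replicate 2 held Xist with Ddx3y at 0.051 and 0.0698 FPKM, and the other 2 libraries held both.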
